A study of Mus musculus with 4 samples.

How the data were processed

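Libraries were made from total RNA of primary mouse hepatocytes with a stranded total RNA kit after column purification and DNase digestion, per the labels' protocols. Each of the 4 groups, KO or WT with or without fatty acids, holds 1 library. The labels call the control cultures untreated, and whether they received a vehicle is not given in the sources used here. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2, StringTie 2.1.3b and the mouse build mm10, without saying what each was used for. The annotation release, the counting rule and its strand setting are not given in the sources used here, so antisense and overlapping genes cannot be told apart from their neighbours.

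The authors deposited 1 table of 45777 genes with an Entrez identifier and a unique symbol each. It gives, per the file headers, whole read counts, FPKM and TPM of every gene in every library. The deposited read counts are not normalized and sum to 85423156 to 97364292. The deposited FPKM are scaled by the authors to length and library, and their sums differ between libraries (668209 in WT untreated, 539602 in KO untreated, 731758 in WT with fatty acids, 557953 in KO with fatty acids). The deposited TPM equal the FPKM rescaled to an equal sum, within 0.001% for genes with a TPM of at least 1. For some genes the FPKM and the counts give different ratios between libraries, so that FPKM may depend on how isoforms were weighted. The signal recognition particle RNAs Rn7s1 and Rn7s2 took 6.20% of reads in WT untreated, 3.94% in KO untreated, 8.20% in WT with fatty acids and 2.60% in KO with fatty acids. Because they and other abundant transcripts differ between libraries, the sum of FPKM is a weak basis for scaling.

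The design fixed before the data were examined assumed FPKM only, and its main results use FPKM. Genes with FPKM of at least 1 in at least 1 library were kept (11927 genes), 1 was added as a pseudocount, and log2(FPKM + 1) was compared between libraries. A difference on this scale understates the change of low genes. With 1 library per group no test has replicates, so a rule of size (2-fold or more) stood in its place. Differences are given relative to the median over the 5903 genes with FPKM of at least 5 in every library. Counts of reads were used for depth and for exact binomial 95% intervals of ratios. These cover counting error only, and reads are not independent molecules. A gene with 0 reads was set to a floor of 3 reads to give its ratio a value, and 3 reads equal a CPM of 0.0308 to 0.0351 here. That value is not a strict lower bound, so the exact lower limit is printed beside it.

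The genes named in the text followed a rule fixed beforehand. It took Dusp6 and every measured Cyp4a gene, and in each comparison the 10 highest and 10 lowest genes with FPKM of at least 5 in the higher library, leaving out predicted genes, pseudogenes and small RNAs by symbol. It added up to 4 members of each described list with the largest difference, and for shared differences 10 genes per direction with the largest smaller difference. Some genes that this rule takes are not reported here. Genes named for the difference between the fatty acid responses and the genes detected in 1 genotype only were chosen after their values were seen. There were 35 gene lists of 790 genes, written beforehand, of which 612 genes were measured. The percentile of a list's median was taken among 10000 random lists matched on mean expression in 20 bins. Genes on several lists are counted in each.

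Other settings fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at FPKM 5, centring on the median, rescaling to an equal sum, quantile normalization, rescaling without the 50 most abundant genes, leaving out predicted genes and small RNAs, a 1.5-fold rule, and a limma fit with additive terms for genotype and fatty acids, which has 1 residual degree of freedom and takes any interaction for noise. After seeing the data, CPM with TMM scaling, an edgeR quasi-likelihood fit of the same additive form on the read counts, and an adjustment for GC content and transcript length were added. The adjustment was a robust spline fit over the 5789 reference genes (98.1%) with a GENCODE M21 transcript, a release on the same build. Coordinates are those of RefSeq on GRCm38.p6, which is mm10, matched by Entrez identifier for 99.8% of compared genes.

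Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16. Steps were tested on simulated data built on the 11927 genes, with 200 genes changed in KO and an assumed spread of 10% between libraries. For KO minus WT in untreated cells the size rule recovered 0% of genes changed 1.5-fold, 40% at 2-fold, 100% at 3-fold and 100% at 4-fold, with 2 of 11727 unchanged genes past it. With fatty acids it recovered 0%, 54%, 96% and 100%, again with 2. A simulated length trend in the KO fatty acid library put 303 unchanged genes past the rule for fatty acids in KO, and 5 after adjustment. That trend was built from the same transcript lengths that the adjustment fits, so its removal was built in. The size of the trend and the library that held it were assumed. The same trend put 247 unchanged genes past the rule for KO minus WT with fatty acids. In the real data the Spearman correlation with length was -0.04 in that comparison and 0.25 for KO minus WT in untreated cells. The real trend thus did not lie where the simulation placed it. The real spread between cultures is unknown.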

Results

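RNA was sequenced from primary mouse hepatocytes, the main cells of the liver, taken from mice lacking the dual specificity phosphatase 6 gene Dusp6 (KO) or from wild-type mice (WT). Dusp6 codes for a cytoplasmic phosphatase that inactivates the mitogen-activated protein kinase ERK. After 3 h in culture, cells were either left untreated or given a mixture of palmitic acid at 0.5 mM and oleic acid at 1 mM for 24 h, a treatment that loads hepatocytes with lipid. The series thus holds 4 groups, KO and WT with and without fatty acids, with 1 library in each. Total reads per library were 87272191 for WT untreated, 85423156 for KO untreated, 89069900 for WT with fatty acids and 97364292 for KO with fatty acids. Of 45777 genes in the table, 11927 reached an FPKM of 1 in at least 1 library and were compared.

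With 1 library per group, no difference below has a replicate check, and no p-value is given for a pair of libraries. A gene was counted as higher or lower when log2(FPKM + 1) differed by 2-fold or more. The deposited scale placed the median gene at different heights in different libraries. Over 5903 genes with an FPKM of at least 5 in every library, the median log2 difference was 0.00 for KO minus WT in untreated cells, 0.38 for KO minus WT with fatty acids, -0.26 for fatty acids minus untreated in WT and 0.16 for fatty acids minus untreated in KO. Log2 differences of single genes are therefore given relative to this median gene, beside the deposited FPKM. Adding the shift of the comparison gives the difference on the deposited scale. The percentile of a gene list places its median among 10000 random lists of equal size matched on expression, and describes these libraries only.

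The targeted gene and the Cyp4a family were examined first, since the study's title names both. Dusp6 (Entrez 67603, mm10 chromosome 10, 99263231 to 99267489) had an FPKM of 40.7 in WT untreated and 77.1 in WT with fatty acids, against 1.42 in KO untreated and 1.11 in KO with fatty acids. In read counts scaled to library totals (CPM), WT exceeded KO by 27.9-fold in untreated cells (exact 95% interval 25.2 to 30.9, from 11235 and 394 reads) and by 70.2-fold with fatty acids (63.1 to 78.2, from 22333 and 348 reads). These intervals cover counting error only. Within WT, Dusp6 was higher with fatty acids by 1.17 on the log2 scale. The level of Dusp6 thus matched the genotype label of every library.

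Cyp4a enzymes hydroxylate fatty acids at the omega position, and most murine Cyp4a genes are classical targets of the nuclear receptor PPARα. Cyp4a14 (Entrez 13119, chromosome 4, 115486200 to 115496158) had an FPKM of 188 in WT and 1.43 in KO without treatment, and of 237 and 1.03 with fatty acids. Cyp4a10 (Entrez 13117, chromosome 4, 115518287 to 115533649) had 228 and 5.61 without treatment, and 253 and 4.88 with fatty acids. The WT to KO ratio in CPM was 127 for Cyp4a14 (exact 95% interval 114 to 141) and 39.6 for Cyp4a10 (37.4 to 42.0) in untreated cells. With fatty acids it was 232 (207 to 261) and 52.5 (49.5 to 55.7). Cyp4a31 was also lower in KO, at an FPKM of 0.285 against 4.89 untreated and 0.173 against 5.06 with fatty acids, as was Cyp4a32, at 1.45 against 12.4 and 1.12 against 14.9. Cyp4a12a and Cyp4a12b, whose expression is male-biased, did not share this pattern. Cyp4a12a was higher in KO in untreated cells (21.5 against 8.83) and lower with fatty acids (8.71 against 12.1), and Cyp4a12b went the same way (8.61 against 4.49, then 2.95 against 5.79). Members of this family are close in sequence and lie side by side on chromosome 4, so reads may be divided among them by the authors' counting.

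**Figure D1:**
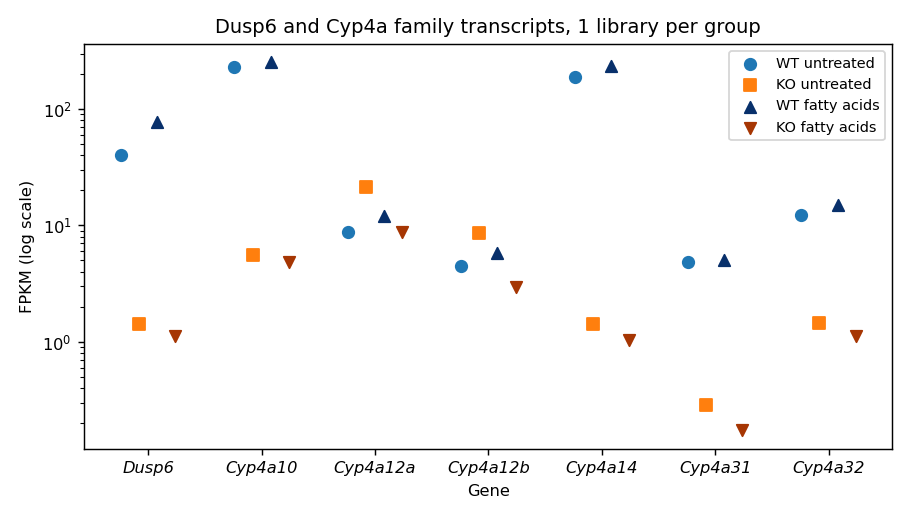
FPKM (log axis) of Dusp6 and the 6 measured Cyp4a genes, with 1 point for each of the 4 libraries and no error bars because each group has 1 library. Dusp6, Cyp4a10, Cyp4a14, Cyp4a31 and Cyp4a32 lie lower in both KO libraries than in both WT libraries, with Cyp4a14 at 1.43 and 1.03 in KO against 188 and 237 in WT.

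The untreated pair shows what loss of Dusp6 went with before any lipid load. In this 1 pair, the KO library had lower transcripts of PPARα-regulated fatty acid oxidation genes and of chemokines. It had higher transcripts of Cyp1a enzymes, acute phase proteins and lipid synthesis genes, but these were not alone. Of 34 gene lists, 19 lay above the central 95% of random lists. Markers of macrophages (median 0.88) and of sinusoidal endothelium (1.09) stood above acute phase proteins (0.62). Beside the Cyp4a genes, the lowest in the KO library were Serpina3c, a serine protease inhibitor (FPKM 0.407 in KO against 40.02 in WT, log2 difference -4.87), the neutrophil chemokines Cxcl1 (8.64 against 135, -3.82) and Cxcl2 (0.690 against 21.7, -3.75), and the retinol saturase Retsat (15.6 against 147, -3.16). They were followed by the peroxisomal bifunctional enzyme Ehhadh (6.60 against 46.7, -2.65), the acyl-CoA thioesterase Acot1 (1.67 against 15.7, -2.65) and the major urinary protein Mup5 (2.68 against 20.7, -2.56), which belongs to a family of near-identical copies. The long non-coding RNA Urml had 4017 reads in KO and none in WT. Against a floor of 3 reads this was 1368-fold more in CPM (exact 95% lower limit 1112). The guanylate-binding protein Gbp2b had 2974 reads in KO and none in WT, 1013-fold more against the same floor (exact 95% lower limit 823). Also higher in KO were Cyp1a1 (FPKM 45.1 against 1.355, log2 difference 4.29) and Cyp1a2 (321 against 45.1, 2.80), both targets of the aryl hydrocarbon receptor. The matricellular protein Ccn2 was at 132 against 9.56 (3.65), the carbonic anhydrase Car3 at 169 against 13.3 (3.57) and Cyp2c70, which makes muricholic acids, at 46.3 against 4.02 (3.24). Id1, an inhibitor of DNA binding, was at 16.4 against 1.03 (3.10), Serpina1e, an alpha-1-antitrypsin copy, at 2236 against 261 (3.09), and the complement gene C8a at 82.7 against 9.86 (2.95).

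By list, PPARα targets and fatty acid oxidation had a median log2 difference of -0.45 over 37 genes (percentile 0), with 11 genes lower by 2-fold or more and 0 higher. Among them the thiolase Acaa1b was at 102 in KO against 281 in WT. Inflammation and chemokine genes had a median of -0.73 (percentile 0), with 11 of 24 lower and 1 higher, including the adhesion molecule Icam1 (4.44 against 24.9) and the monocyte chemokine Ccl2 (4.60 against 23.0). Genes of the periportal zone had 5 of 16 lower and 2 higher, with a median of -0.22 at percentile 2.72. Among them were the urea cycle genes Ass1 (91.5 against 307), Cps1 (22.0 against 69.8) and Asl (27.4 against 114). Targets of p53 had a median of -0.46 with 4 of 21 lower and 0 higher, led by Gadd45b (12.3 against 39.1), and genes of endoplasmic reticulum stress and ATF4 had a median of -0.36 with 2 of 30 lower, the chaperones Dnajb9 and Manf.

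Of the 34 lists with at least 3 measured genes, 19 lay above the central 95% of random lists in this comparison and 5 below. A place above random lists alone thus did not set a list apart here. Among lists with medians above nearly all random lists were acute phase proteins (0.62, 6 of 24 higher, 0 lower), where the serum amyloid genes Saa1 and Saa2 were at 3871 and 3208 in KO against 797 and 626 in WT. De novo lipogenesis had a median of 0.43 with 4 of 24 higher and 0 lower. These were the stearoyl-CoA desaturase Scd1 (424 against 72.3), the acetyl-CoA carboxylase Acaca (27.3 against 7.76), the desaturase Fads1 (84.6 against 35.6) and the fatty acid synthase Fasn (35.9 against 16.8). Cholesterol synthesis genes had a median of 0.61 with 6 of 25 higher and 0 lower, among them Nsdhl (12.8 against 3.25), Dhcr7 (10.8 against 2.90) and the squalene synthase Fdft1 (22.5 against 8.97). Pericentral genes had a median of 0.73 with 4 of 13 higher, including Cyp2a5 (1359 against 397) and Rgn (219 against 57.2). Genes of drug metabolism had a median of 0.52 with 9 of 32 higher and 4 lower (2 lower after adjustment for GC content and length), the latter including the nuclear receptor Nr1i3, known as CAR (1.63 against 11.4). NRF2 targets had a median of 0.23 with 2 of 30 higher, the glutathione transferases Gstm2 (55.5 against 11.4) and Gstm3 (50.3 against 10.7). Dedifferentiation markers, which rise when hepatocytes are kept in culture, had a median of 0.38 with 8 of 30 higher, including vimentin (Vim, 124 against 29.0). ERK response genes had a median of -0.06 (percentile 17.3) with members on both sides. Hbegf (12.3 against 3.46), Lif (6.13 against 1.52) and Fosl2 (15.9 against 6.44) were higher and Dusp5 (5.49 against 18.4) was lower. Kinases and phosphatases of the MAPK pathways had a median of 0.28 (percentile 98.7), which came inside the central 95% of random lists with a pseudocount of 5 and after adjustment for GC content and length (median 0.19, percentile 94.1). Mapk3, which codes for ERK1, was at 9.85 against 3.62.

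Markers of cells other than hepatocytes were also higher in this KO library. Kupffer cell and macrophage markers had a median of 0.88 (5 of 16 higher, 0 lower), with Clec4f at 7.62 against 0.677 and C1qc at 13.1 against 3.29, and sinusoidal endothelial markers had a median of 1.09 (5 of 8 higher), with Cdh5 at 5.44 against 0.732. The lower chemokines and the higher acute phase, matrix and dedifferentiation genes, Vim among them, stand beside this difference in marker level. In all, 426 genes were higher and 249 lower in KO on the deposited scale, against 423 and 250 relative to the median gene. Rescaling every library to the same sum gave 1253 and 181, and quantile normalization 343 and 313.

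With fatty acids, the same contrast asks how KO and WT cells differ under lipid load. Chemokine and PPARα target genes were again lower in KO and cholesterol synthesis genes again higher. The lowest genes in KO were Il23a, the p19 subunit of interleukin 23 (FPKM 0.192 in KO against 140.1 in WT, log2 difference -7.26), Cyp4a14 (-7.25), Cxcl2 (0.561 against 157, -7.04), Cxcl1 (13.6 against 684, -5.93), Cyp4a10 (-5.81) and Serpina3c (0.182 against 46.3, -5.70). After Dusp6 itself (-5.58) came the small GTPase Rnd1 (6.15 against 202, -5.21), the hydroxycarboxylic acid receptor Hcar2 (1.03 against 22.2, -3.89) and the chemokine Ccl7 (0.941 against 19.2, -3.76). On the log2(FPKM + 1) scale, highest in KO was Cyp1a1 (56.0 against 0.687, 4.70), though Urml and Gbp2b had larger ratios in reads. Urml (3563 reads against none, 1086-fold against the floor, exact 95% lower limit 883) and Gbp2b (4134 reads against none, 1261-fold against the floor, exact 95% lower limit 1025) were again detected in KO and without a read in WT. The tight junction gene Cldn4 (92.8 against 5.79, 3.41), the lysosomal glycoprotein gene Gpnmb (22.8 against 1.20, 3.06), Cyp1a2 (303 against 31.0, 2.87), Car3 (174 against 17.9, 2.84), Cyp2c70 (51.1 against 4.68, 2.82) and Jup, which codes for plakoglobin (18.8 against 1.75, 2.47), followed. Trdj1, a short T cell receptor segment, was at 35.1 against 2.68 but rests on 200 and 15 reads.

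PPARα targets had a median of -0.80 (percentile 0), with 13 of 37 genes lower by 2-fold relative to the median gene and 0 higher. Their median on the deposited scale was -0.42, with 8 lower and 1 higher, against -0.45 in untreated cells. Ehhadh was at 6.59 in KO against 49.96 in WT, Acot1 at 2.20 against 18.4, and Pdk4, a kinase that holds back pyruvate oxidation, at 12.0 against 103. Inflammation genes had a median of -1.55 (percentile 0), with 20 of 24 lower and 0 higher (deposited scale -1.17, 15 lower, 1 higher), including Ccl2 (6.33 against 56.0). ERK response genes had a median of -0.71 (percentile 0), with 8 of 20 lower and 0 higher (deposited scale -0.33, 7 lower, 0 higher), led by Egr1 (2.26 against 7.56), Dusp5 (8.49 against 22.8), Phlda1 (8.08 against 20.6) and Fos (1.04 against 3.47). Lipid droplet and lipolysis genes had a median of -0.58 with 7 of 19 lower and 1 higher, but -0.20 with 3 lower and 3 higher on the deposited scale. The lipase inhibitor Hilpda was at 21.8 against 102, and Cidea was higher at 5.15 against 0.478. Fatty acid uptake and lipoprotein genes had a median of -0.33, with 6 of 26 lower and 2 higher, but 0.04 on the deposited scale, with 3 lower and 3 higher, and the adjustment for GC content and length also gave 3 and 3. The lower ones included Apoa4 (53.6 against 166) and Fabp2 (22.3 against 64.8), and the higher ones included the transporter Slc27a4 (16.8 against 4.28). Periportal genes had a median of -0.78, with 6 of 16 lower and 0 higher (deposited scale -0.40, 5 lower, 2 higher), including Cps1 (18.6 against 97.1), Asl (30.5 against 98.7) and the gluconeogenic gene Pck1 (0.916 against 8.89). Gluconeogenesis and insulin response genes had a median of -0.57 (deposited scale -0.20), with Tat at 14.7 against 49.6. Targets of p53 had a median of -0.52 with 7 of 21 lower and 0 higher (deposited scale -0.14, 5 lower, 1 higher), including Gadd45b (15.0 against 144) and Cdkn1a (14.2 against 36.1).

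Cholesterol synthesis genes stood highest, with a median of 1.13 (percentile 100), 13 of 25 higher by 2-fold and 0 lower (deposited scale 1.503, 18 higher, 0 lower). Farnesyl diphosphate synthase (Fdps) was at 259 in KO against 36.7 in WT, Fdft1 at 30.4 against 6.80 and Mvd at 9.13 against 1.56. Lipogenesis genes had a median of 0.40, a place among random lists that was lost with a pseudocount of 5, with 5 of 24 higher and 3 lower. The split was 8 and 1 on the deposited scale (median 0.78), and 4 and 4 after adjustment for GC content and length. The higher genes included Fads2 (91.8 against 24.0), Agpat2 (39.5 against 11.2), Fads1 (75.7 against 22.5) and the transcription factor gene Srebf1 (23.5 against 6.98). Acute phase proteins were split, with 4 of 24 higher and 5 lower, and their median was -0.14 (deposited scale 0.24, 7 higher, 4 lower). Saa1 (4575 against 1049) and Saa2 (4014 against 828) were higher, and Crp (7.08 against 25.5) and Lcn2 (119 against 346) were lower. Genes of endoplasmic reticulum stress and ATF4 had a median of 0.01 with 3 of 30 higher and 5 lower (deposited scale 0.39, 7 higher, 2 lower), with the serine synthesis gene Phgdh (21.7 against 3.01) higher and Dnajb9 (31.2 against 89.4) lower. Mitochondrially encoded genes had a median of -0.92 with 5 of 13 lower (deposited scale -0.55, 2 lower), including ND2 (23.8 against 53.5). Macrophage markers had a median of -0.20 (percentile 22.1), with Marco (3.64 against 25.3) and Adgre1 (4.03 against 12.4) lower and Clec4f (7.82 against 1.81) higher, and endothelial markers one of -0.30 (percentile 29.7). These medians were 0.18 and 0.08 on the deposited scale. Red blood cell markers were lower in KO (median -1.05, percentile 0.125, 3 of 5 lower and 1 higher; deposited scale -0.68), and lymphocyte and neutrophil markers had a median of -0.54 (deposited scale -0.17) over 5 genes.

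Which direction held more genes depended on the scale. On the deposited scale, 1172 genes were higher and 498 lower in KO, whereas relative to the median gene 372 were higher and 1006 lower. The corresponding counts were 3340 and 360 after rescaling every library to the same sum, 510 and 734 after quantile normalization, 826 and 1082 after rescaling without the 50 most abundant genes, and 664 and 975 from read counts with TMM scaling. Adjustment for GC content and transcript length gave 331 and 951.

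The pairs of KO and WT libraries in each medium share no library, so their differences can be set side by side. The genes that stood apart in both included Cyp1a1, Urml, Gbp2b, Car3, Cyp2c70, Cyp1a2 and Id1 on the higher side, joined by the steroid 21-hydroxylase Cyp21a1 (FPKM 10.4 and 11.3 in KO against 0.824 and 0.813 in WT), the vasopressin receptor Avpr1a (31.1 and 28.2 against 4.54 and 3.16) and neuropeptide Y (Npy, 14.7 and 17.3 against 1.71 and 2.35). On the lower side were Cyp4a14, Cyp4a10, Serpina3c, Dusp6, Cxcl1, Cxcl2, Retsat, Ehhadh, Acot1 and Mat1a, the liver methionine adenosyltransferase (41.4 and 43.8 against 247 and 252). On the deposited scale, 214 genes were higher in KO in both media and 160 were lower, against 41.9 and 10.4 for independent lists of the same lengths. Relative to the median gene the counts were 145 and 186, against 13.2 and 21.1. Across the 11927 genes, the genotype differences in the 2 media had a Pearson r of 0.51 and a Spearman correlation of 0.38. Genes are not independent replicates, so no p-value is given. Nothing in the labels says that the libraries of a genotype came from separate animals.

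**Figure D2:**
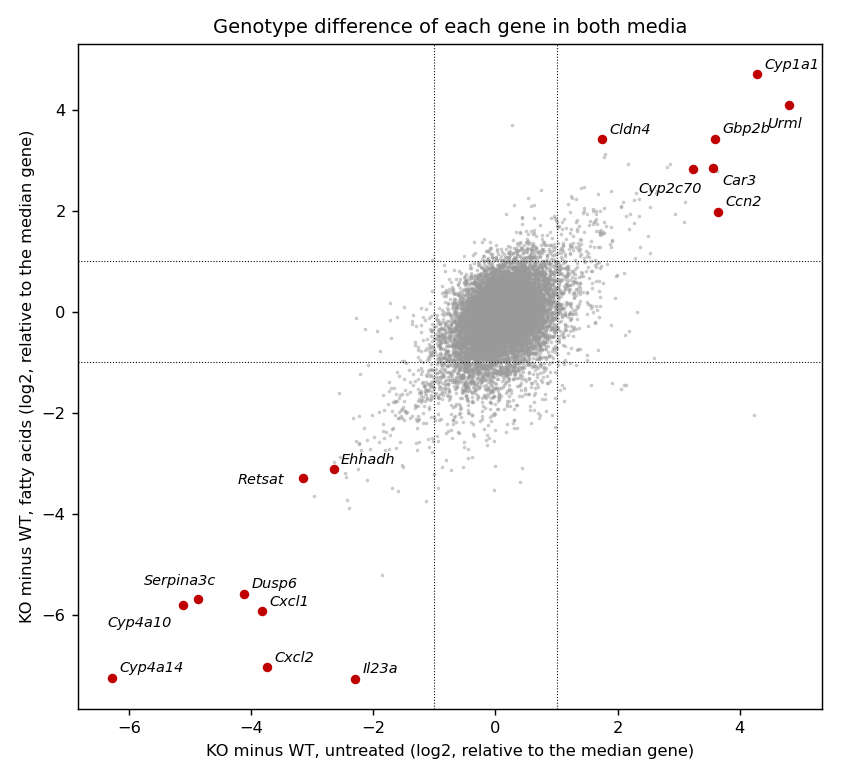
Each point is 1 of 11927 genes, with the KO minus WT log2 difference in untreated cells on the x axis and with fatty acids on the y axis, both relative to the median gene. Dotted lines mark 2-fold and named genes are in red. Cyp4a14, Cyp4a10, Cxcl1, Cxcl2 and Dusp6 lie low in both media and Cyp1a1 and Car3 high in both, with r = 0.51 across genes.

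Adding fatty acids to WT hepatocytes went with higher transcripts of chemokines and of markers of macrophages, and lower transcripts of cholesterol synthesis genes. PPARα targets lay above the median gene, as did most lists. The highest was Il23a (FPKM 140.1 with fatty acids against 5.73 without, log2 difference 4.65), followed by Rnd1 (202 against 23.3, 3.33), Cxcl2 (157 against 21.7, 3.07), Id3 (145 against 20.9, 3.00), Tcim (18.5 against 2.26, 2.85), the EGF receptor ligand Areg (13.4 against 1.78, 2.63), Pdk4 (103 against 19.2, 2.62), Cxcl1 (684 against 135, 2.60), the scavenger receptor Marco (25.3 against 4.83, 2.44) and the thioredoxin inhibitor Txnip (411 against 90.9, 2.43). Lowest were the retinoic acid hydroxylase Cyp26a1 (1.08 against 6.62, -1.61), Phgdh (3.01 against 13.7, -1.61), the tropomyosin Tpm2 (4.69 against 19.3, -1.57), Palld (9.95 against 37.4, -1.55), Sco2 (2.76 against 11.9, -1.51), the histone gene H4f16 (2.65 against 11.2, -1.47), the FGF receptor Fgfr4 (1.84 against 8.26, -1.44), Hhipl1 (1.08 against 5.72, -1.43), the heat shock gene Hspa4l (4.80 against 17.2, -1.39) and the metallothionein Mt2 (8.65 against 29.2, -1.39). Hspa4l was under 2-fold in read counts with TMM scaling, at -0.64.

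Inflammation genes had a median of 1.02 (percentile 100), with 12 of 24 higher and 0 lower (deposited scale 0.75, 8 higher), including Ccl7 (19.2 against 3.58) and the NF-κB inhibitor Tnfaip3 (16.1 against 4.64). Macrophage markers were higher by a like amount (median 1.17, 12 of 16 higher, 0 lower, against 0.91 and 7 higher on the deposited scale), with Adgre1 at 12.4 against 4.43 and Lyz2 at 88.1 against 38.3. Endothelial markers had a median of 0.83 and red blood cell markers one of 1.02 (deposited scale 0.57 and 0.76). PPARα targets had a median of 0.43 (percentile 100; 0.17 on the deposited scale), with 3 of 37 higher and 0 lower. They included Pdk4 and Angptl4, an inhibitor of lipoprotein lipase (120 against 55.7). Fabp1 was at 1217 against 732. The Cyp4a family had a median of 0.54 (deposited scale 0.28) with 0 of 6 past 2-fold. Hilpda (102 against 37.4) was the 1 lipid droplet gene of 19 past 2-fold, and Fabp5 (290 against 88.8), Fabp4 (20.4 against 7.58) and Apoe (3237 against 1524) were the 3 of 26 uptake and lipoprotein genes. ERK response genes had a median of 0.54 with 5 of 20 higher and 0 lower (deposited scale 0.28, 3 higher), among them Ier3 (104 against 31.8), Junb (148 against 59.0) and Fos (3.47 against 1.01). Mitochondrially encoded genes had the highest list median, 1.3448, with 9 of 13 higher (deposited scale 1.08, 8 higher), including ND1 (420 against 164) and COX2 (842 against 348). The gluconeogenic genes G6pc (8.25 against 2.28) and Pck1 (8.89 against 3.58) were higher, as was hepcidin (Hamp, 87.1 against 25.2).

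Cholesterol synthesis genes had a median of -0.55 (percentile 0), with 3 of 25 lower by 2-fold relative to the median gene and 0 higher. The deposited scale gave -0.81 with 8 lower, and adjustment for GC content and length -0.36 with 2 lower. They included Fdps (36.7 against 105.5) and the lanosterol synthase Lss (1.72 against 5.91). Genes of endoplasmic reticulum stress and ATF4 had a median of -0.18 (percentile 0.46, a place lost under TMM scaling), with 4 of 30 lower and 1 higher (deposited scale -0.45, 7 lower, 1 higher). The lower ones were Phgdh, the serine synthesis gene Psat1 (32.9 against 96.8), Sesn2 (5.49 against 18.1) and Atf5 (26.6 against 71.1). Lipogenesis genes had a median of 0.01 (percentile 57.3; deposited scale -0.26). Of the 34 lists with at least 3 measured genes, 24 lay above the central 95% of random lists in this comparison. Hepatocyte identity was among them, with a median of 0.55 (deposited scale 0.29) and 1 of 33 genes past 2-fold, so a place above random lists did not set a list apart here. On the deposited scale 212 genes were higher and 267 lower with fatty acids in WT, and relative to the median gene 426 and 78. Rescaling every library to the same sum gave 207 and 638, quantile normalization 354 and 108, rescaling without the 50 most abundant genes 495 and 349, TMM scaling of read counts 413 and 169, and adjustment for GC content and transcript length 390 and 72.

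In KO hepatocytes the fatty acid difference was made up almost wholly of lower genes, and the medians of the inflammation and PPARα lists lay near the median gene. Among the lowest were the RNA-binding protein gene Pcbp2 (10.6 with fatty acids against 54.5 without, log2 difference -2.42), the kinase Aak1 (0.347 against 5.27, -2.38), the phosphatase subunit Ppp2r2a (4.32 against 22.7, -2.32), the largest RNA polymerase II subunit Polr2a (2.33 against 13.5, -2.29), Raver1 (0.659 against 6.10, -2.26), nucleolin (Ncl, 10.7 against 49.1, -2.26), Olfr1033 (5.62 against 27.0, -2.24), the poly(A)-binding protein Pabpc1 (62.0 against 263, -2.23) and the translation regulator Eif4ebp2 (2.37 against 12.9, -2.20). The highest were Dpm1 (13.9 against 4.61, 1.25) and Dedd2 (6.67 against 2.08, 1.15). Read counts with TMM scaling put Dedd2 under 2-fold, at 0.49. The next 8, Gps2, Ddrgk1, Procr, Psma3, Zbed5, Rps24, Defb36 and Bnip1, lay between 0.75 and 0.89, and Zbed5 changed sign under TMM scaling of read counts. On the deposited scale 20 genes were higher and 393 lower, and relative to the median gene 12 and 602.

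Inflammation genes had a median of -0.16 (percentile 31.5) with 0 of 24 past 2-fold in either direction, and Cxcl1 was at 13.6 with fatty acids against 8.64 without. PPARα targets had a median of 0.05 (percentile 77.6; deposited scale 0.21), with Pdk4 lower (12.0 against 25.8) and no other member past 2-fold. Cyp4a12a (8.71 against 21.5) and Cyp4a12b (2.95 against 8.61) were the 2 of 6 Cyp4a genes lower by 2-fold. Cholesterol synthesis genes had a median of -0.08 (percentile 17.5), or 0.08 on the deposited scale, with Srebf2, the transcription factor of this pathway (3.77 against 9.30), and Dhcr7 (5.19 against 10.8) lower. Among lipogenesis genes (median -0.19, percentile 0.86) 3 of 24 were lower, the transcription factor Mlxipl (4.19 against 9.08), Scd1 (232 against 424) and Me1 (44.5 against 81.4). None of the 24 was past 2-fold on the deposited scale, and after adjustment for GC content and length 1 was. This list lost its place among the lowest random lists once differences were adjusted for GC content and length (median 0.01, percentile 53.02), and also under TMM scaling and without a filter. Apob (94.5 against 244), the main structural protein of VLDL, Fn1 (40.7 against 135), the insulin receptor Insr (4.83 against 11.5), the cell cycle inhibitor Cdkn1a (14.2 against 41.4), Phlda1 (8.08 against 30.8) and Egr1 (2.26 against 9.27) were also lower. Of these, Apob and Insr were under 2-fold after adjustment for GC content and length, at -0.68 and -0.60. Mitochondrially encoded genes had a median of -0.59 (percentile 0) with 3 of 13 lower (deposited scale -0.42, 2 lower), namely ND4, ND5 and ND2. Macrophage markers had a median of -0.00 (percentile 88.7).

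Long transcripts were lower with fatty acids in KO. The Spearman correlation of the difference with transcript length over 5789 genes was -0.55, against -0.17 in WT. For KO minus WT it was 0.25 in untreated cells, with medians from -0.16 in the shortest group to 0.21 in the longest, and -0.04 with fatty acids. The 2 comparisons that use the untreated KO library thus had the largest correlations with length. Of 10 groups of genes by length, the 1 with the longest transcripts (median 7022 nt) had a median difference of -0.48, and the shortest (692 nt) 0.16. After adjustment for GC content and length, 15 genes were higher and 331 lower. The Spearman correlation with GC content was 0.21 for fatty acids in KO and -0.13 in WT. For KO minus WT it was 0.02 in untreated cells and 0.24 with fatty acids, so that last comparison was not free of such trends.

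**Figure D3:**
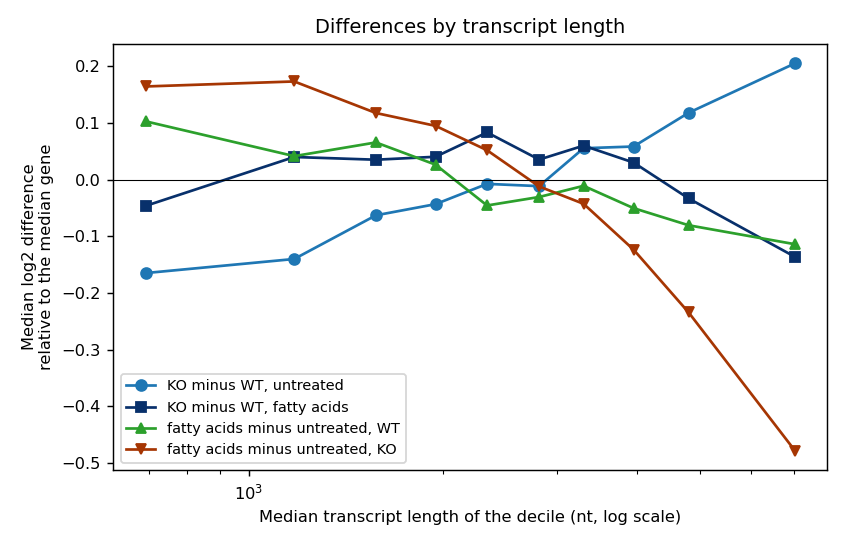
Median log2 difference relative to the median gene (y axis) in 10 groups of genes ordered by transcript length (x axis, median length in nt, log scale), with 1 line for each of the 4 comparisons. Fatty acids minus untreated in KO goes from 0.16 in the shortest group to -0.48 in the longest.

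The fatty acid differences of the 2 genotypes had little in common. On the deposited scale 1 gene was higher and 16 were lower in both, against 0.355 and 8.80 for independent lists, and relative to the median gene 1 and 9, against 0.429 and 3.94. The gene higher in both was Dpm1, which codes for a subunit of dolichol-phosphate mannose synthase (12.0 against 2.53 in WT, 13.9 against 4.61 in KO). Lower in both were Palld (9.95 against 37.4 in WT, 8.28 against 35.2 in KO), Aak1, the nucleotide sugar transporter Slc35d1, the actin-binding genes Actn4 and Mical2, and others. Across genes, Pearson r was 0.04 and the Spearman correlation 0.03. The fatty acid differences of KO and WT were at least 2-fold apart in 1236 genes on the deposited scale. Il23a (4.65 in WT, -0.36 in KO), Rnd1 (3.33 and -0.06), Cxcl2 (3.07 and -0.28) and Id3 (3.00 and 0.13) were higher in WT alone, while Phgdh (-1.61 and 0.17), Cyp26a1 (-1.61 and 0.06) and Fdps (-1.24 and 0.38) were lower in WT alone. This count carries the noise of all 4 libraries, and the difference between genotypes was not tested.

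**Figure D4:**
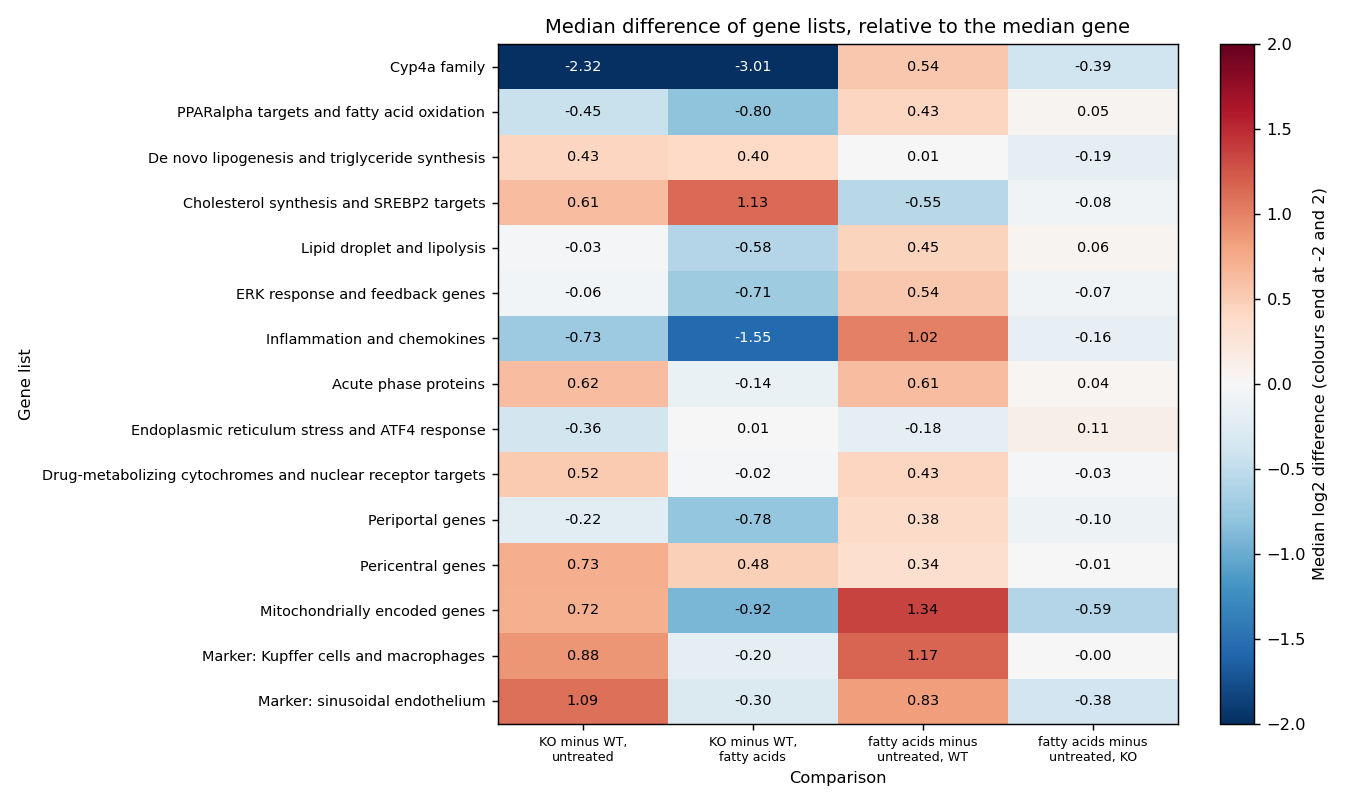
Median log2 difference of 15 gene lists (rows) in the 4 comparisons (columns), relative to the median gene, as colour and printed value. Inflammation and chemokine genes read -0.73 and -1.55 for KO minus WT, 1.02 for fatty acids in WT and -0.16 for fatty acids in KO.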

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

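The single genes here, all taken by the naming rule, differed past 2-fold in opposite directions in the 2 genotypes or the 2 media. The lists are those whose medians stood apart from random lists in opposite directions. Genes outside the naming rule could do so too. For the fatty acid difference these included Zfp36l1 (1.49 in WT, -2.08 in KO) and Zfp36 (2.15 and -1.17). The difference between groups was not tested, since each group is 1 library. Values are relative to the median gene, and all tests on inflammation genes in this part were chosen after the results were seen.

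The fatty acid difference was opposite in WT and KO for Pdk4 (2.62 and -1.20, 3.83 apart), hepcidin Hamp (2.01 and -1.04, 3.06 apart), Egr1 (1.12 and -1.82, 2.93 apart), ND2 (1.57 and -1.11, 2.69 apart) and ND4 (1.14 and -1.28, 2.41 apart). The mitochondrially encoded list was at 1.3448 in WT and -0.59 in KO, 1.93 apart. The genotype difference was opposite without and with fatty acids for Hamp (1.56 and -1.45, 3.01 apart), Egr1 (1.12 and -1.77, 2.88 apart), ND2 (1.12 and -1.51, 2.64 apart) and CYTB (1.22 and -1.01, 2.23 apart). By list it was opposite for mitochondrially encoded genes (0.72 and -0.92, 1.64 apart), for signals of the fed and unfed state and hepatokines (0.31 and -0.35, 0.66 apart) and for hepatocyte identity (0.15 and -0.22, 0.38 apart). The direction of these last 2 lists with fatty acids depended on whether differences were centred on the median gene. Relative to it, both medians stayed below 0 under every alternative scaling. They ran from -0.42 to -0.17 for hepatokines and from -0.47 to -0.14 for hepatocyte identity. Without that centring, quantile normalization also put them below 0, at -0.14 for hepatokines and -0.11 for hepatocyte identity. So did TMM scaling for hepatocyte identity (-0.20) and leaving out the 50 most abundant genes for hepatokines (-0.20). A pseudocount of 0.1, also without centring, left both above 0, at 0.10 for hepatokines and 0.18 for hepatocyte identity. The median gene lay at 0.40 there, so both were still below it. The untreated hepatocyte identity median came inside the central 95% of random lists after quantile normalization, TMM scaling and the GC and length adjustment, and that with fatty acids under a pseudocount of 0.1, the FPKM 5 filter, quantile normalization and TMM scaling. The hepatokine list did so untreated after quantile normalization, and with fatty acids under a pseudocount of 0.1, quantile normalization and rescaling without the 50 most abundant genes. Their deposited medians were not opposite, at 0.31 and 0.02 and at 0.16 and 0.15, while those of the mitochondrial list were (0.72 and -0.55). The single genes kept opposite signs on the deposited scale, but Egr1 and ND4 in WT, Hamp and ND2 in KO, and CYTB with fatty acids were under 2-fold there. The mitochondrial transcripts took 0.903% of reads in WT untreated, 1.21% in KO untreated, 2.02% in WT with fatty acids and 1.43% in KO with fatty acids.

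Inflammation genes were higher with fatty acids in WT (median 1.02) and lower in KO than in WT in both media (-0.73 and -1.55). A trend with GC content and transcript length is argued against as the whole cause, since the WT median stayed at 1.02 after adjustment. Fewer macrophages in the untreated KO culture is argued against, since macrophage markers were higher there, with a median of 0.88. In the fatty acid pair the marker median was -0.20, which is small beside -1.55 but below 0 (0.18 on the deposited scale), and red blood cell markers were at -1.05, so a smaller share of macrophages there cannot be told apart from a genotype effect by these markers. In WT, macrophage markers were higher with fatty acids by 1.17, as a larger share of macrophages in that culture would give, so this and a response of the hepatocytes themselves, which was not tested, both stay open.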

How the results depend on the processing

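TMM scaling, edgeR and the GC and length adjustment were chosen after seeing the data. Dusp6 stayed lower in KO by over 2-fold in both media under all alternatives, and the correlation of genotype differences kept its sign within 1.5 times. No filter changes no count of a single comparison, since a gene under FPKM 1 everywhere cannot differ 2-fold on this scale, and moves the genes whose responses were 2-fold apart from 1236 to 1263. Symbols are unique, so the choice of row per symbol was void. No paired analysis was possible because the labels number no replicates, though the additive fits below hold medium or genotype as a block. Leaving out a library removes every comparison that uses it. The cause was not tested for the values below beyond what each alternative does by construction. Counts are higher then lower, for KO minus WT untreated, KO minus WT with fatty acids, fatty acids in WT and fatty acids in KO, where they moved by over 1.5 times.

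A pseudocount of 0.1 gave 942 and 478, 1960 and 827, 467 and 804, and 118 and 774, with 769 shared genotype genes, 122 shared fatty acid genes and 2228 genes whose responses were 2-fold apart. A pseudocount of 5 gave 141 and 98, 426 and 177, 79 and 48, and 2 and 82, with 170, 3 and 382. The 1.5-fold rule gave 1644 and 799, 3562 and 1084, 643 and 1964, and 318 and 1173, with 1201, 268 and 4221. Centring gave 372 and 1006 for KO minus WT with fatty acids, 426 and 78 in WT, 12 and 602 in KO, and 10 shared fatty acid genes. Rescaling to an equal sum gave 1253 higher untreated, 3340 higher with fatty acids, 638 lower in WT, 38 higher in KO, and 764 and 59 shared. Quantile normalization gave 510 higher with fatty acids, 354 and 108 in WT, and 8 shared fatty acid genes. Without the 50 most abundant genes there were 778 higher untreated, 1082 lower with fatty acids, 495 higher in WT, 42 and 878 in KO, and 48 shared fatty acid genes. TMM scaling gave 664 and 975, 413 and 169 in WT, and 11 higher in KO. The GC and length adjustment gave 331 and 951, 390 and 72 in WT, and 8 shared fatty acid genes. Without predicted genes and small RNAs 307 were lower with fatty acids, 128 higher in WT and 5 higher in KO, and with the FPKM 5 filter 8 were higher in KO.

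At an adjusted p under 0.05 the additive fits gave 843 genes (limma) and 655 (edgeR) for genotype, and 56 and 4 for fatty acids. These fits assume that the libraries of a genotype are independent, which the labels do not say, and take the interaction as error. Their adjusted p therefore does not measure spread between animals, and these are not counts of established differences. The correlation of fatty acid differences was -0.0100 with a pseudocount of 5, 0.0784 after quantile normalization, 0.0676 without the 50 most abundant genes, 0.0713 without predicted genes, 0.0909 with TMM and -0.0486 after adjustment. There were 72 list medians outside the central 95% of random lists, checked under each alternative for which a percentile was available. None went to the opposite side, 750 values stayed outside and 38 did not. Centring shifts a list and its random lists alike, so it could not move any percentile, and its checks were void. Of 98 differences of single genes, none past 2-fold changed sign, 1044 values stayed on their side of 2-fold, 23 dropped under it and 11 went past it.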

Other observations

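The tests on the genotype differences in this part, and the test of a uniform shift with fatty acids in KO, were chosen after the results were seen, while the bound for the length and GC test was written before its result. Among lists not yet described, interferon-stimulated genes had a median of 0.40 in KO untreated cells (percentile 98.9, 5 of 19 higher by 2-fold, 0 lower), with Isg15 at 9.74 against 1.90 and Irf7 at 10.6 against 3.16. The median came inside the central 95% of random lists with a pseudocount of 5, without a filter, after quantile normalization and after adjustment for GC content and length (0.26, percentile 93.2). With fatty acids it was -0.16 (percentile 38.8), or 0.21 on the deposited scale. Cell cycle genes had a KO minus WT median of 0.33 untreated (percentile 96.3) and 0.49 with fatty acids (percentile 100; deposited scale 0.87), where Mcm4 was at 7.26 against 1.54 and Ccne1 at 7.61 against 1.80. Bile acid synthesis and transport genes had medians of -0.12 and -0.41, the latter -0.03 on the deposited scale and inside the central 95% under the filter at FPKM 5, with Baat, which conjugates bile acids, at 4.15 against 10.97 untreated and 3.60 against 10.9 with fatty acids. Matrix genes had a median of 0.74 in untreated KO cells, with Thbs1 at 19.2 against 4.05. Peroxisome biogenesis genes lay near the median gene (0.02, percentile 33.4), with Pxmp2 lower at 9.26 against 22.9.

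Markers of stellate cells (median 0.78, 4 genes), cholangiocytes (1.23, 4 genes) and lymphocytes and neutrophils (0.11, 5 genes) in untreated KO cells rested on few genes, and red blood cell markers were at -0.07. The stellate median lost its place with a pseudocount of 5 and the cholangiocyte median without a filter. Several cholangiocyte markers, Spp1 and Cldn4 among them, can also be made by hepatocytes in culture. Genes with a sex bias in liver had a median of 0.43, a place lost without a filter, with Selenbp2 at 36.2 against 6.57 and Cyp2a4 at 26.0 against 7.16. This list pools genes biased toward either sex, and these named genes are biased toward opposite sexes. Its median therefore gives no direction of sex bias. Nnt, which lacks several exons in the C57BL/6J mouse, was lower in both KO libraries (3.68 against 9.18 untreated, 3.18 against 8.41 with fatty acids). The 13 measured neighbours of Dusp6 had a median of 0.44 untreated, a place lost with a pseudocount of 5 and under the filter at FPKM 5, and -0.09 with fatty acids (0.29 on the deposited scale).

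Fatty acids in KO went with many lower genes and few higher ones. A trend with transcript length and GC content between the KO libraries is argued against as the whole cause, because 331 lower genes against 15 higher stayed past 2-fold after adjustment, above the bound written before that result. It was part of the pattern, since the count was 602 before. A uniform shift from a few abundant transcripts that lowered all others is argued against because the median gene lay 0.16 above 0 on the deposited scale. A difference in RNA quality that annotated length does not capture, and an effect of fatty acids in cells without Dusp6, stay open, and neither was tested.

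Genotype differences recurred in both media, and a hypothesis is that part of them may come from genetic background other than Dusp6. There were 9 genes with at least 100 reads in both libraries of one genotype and at most 3 in both of the other, against 1 gene between media. The bound was 10 genes, and the count fell short of it. That bound was itself written after the results were seen, so a count this close to it cannot argue against the explanation. Allowance for counting spread was also added only after the count was seen, and the explanation stays open. The 9 genes lie on 8 chromosomes and were Urml, Gbp2b, Schip1, Col9a2, Gnasas1, Gm4742 and Serpina3e-ps (with reads in KO) and Fmr1nb and Gm36559 (with reads in WT). Nnt, the only gene of the C57BL/6J deletion list fixed beforehand, had log2 differences of -1.12 untreated and -1.55 with fatty acids. A single gene cannot tell background from an effect of Dusp6 loss. DNA carried along with the knockout allele was examined within 10 Mb of Dusp6. There, 2 of 53 genes, 3.77% (exact 95% interval 0.460% to 13.0%), were among the shared differences, against 2.76% elsewhere. The window held 53 compared genes, so whatever its effect its own genes could not have made up most of the shared differences. The 328 shared differences outside it therefore do not tell whether DNA in the window altered its own genes. Whether genes in the window were affected more often cannot be told, as 53 genes are too few to decide. This reading by interval was also adopted after the value was seen. An effect of such DNA on genes elsewhere was not tested and stays open. An effect of Dusp6 loss itself remains among the open explanations, as does a difference between the animals used.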
